A study of Drosophila melanogaster with 12 samples.

How the data were processed

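RNA was measured in eye imaginal discs of wandering larvae of Drosophila melanogaster, with the antennal part of the disc removed per the labels. Total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of it, per the labels' protocols. The 12 arrays fall into 4 groups of 3. The Runt group expressed wild-type Runt under the ro-Gal4 driver, and the Runt G163R group expressed the Runt protein with that amino acid change under the same driver. The sens mutant group was homozygous for the elements the labels name DF2RES and E1, and its control group was heterozygous for both. Nothing in the labels says that replicates came from separate crosses or animals, so p-values measure only the spread between these samples, which may be technical.

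The deposited values are on a log2 scale, as judged from their range of 1.63 to 15.4 and from near-equal quantiles in all 12 arrays. Per the submitters' processing notes, MAS5, GCRMA and affy were used, with no role or version given there; the background correction and normalization steps behind these log2 values are not given in the sources used here. Array medians lay between 2.59 and 2.67, because most probe sets sit in a dense floor below about 3. Differences between values near this floor are compressed. Between 38.3% and 39.9% of probe sets exceeded a log2 value of 5 on each array. Every sample column of the table was used.

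The table holds 18952 probe sets, of which 183 are manufacturer's controls. In the platform annotation used here 13647 probe sets have 1 gene, 402 have several and 4720 are unnamed. Symbols were compared through gene identifiers with the RefSeq annotation of assembly Release 6 plus ISO1 MT, which was used for names, chromosome arms and gene neighbourhoods only. No gene was named from a probe set with several genes. The genes run and w have no named probe set in this annotation, so the amount of Runt transcript could not be used to check the labels.

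Probe sets above the 40th percentile of their array in at least 3 of 12 arrays were kept, which left 11470 probe sets and 8225 genes. A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that the groups shared 1 estimate of the spread. The contrasts were Runt minus Runt G163R, sens mutant minus control, and the difference between these contrasts. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all kept probe sets, and a probe set was called at an adjusted p under 0.05. Every adjusted p given for a gene comes from this limma test. Standard errors (SE) are those of the moderated fit. Calls in both comparisons were compared per pair of directions with Fisher's exact test, with 4 tests adjusted together.

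A set of 27 gene lists, 19 of genes by function and 8 of markers for other cell types, was fixed before the data were examined. Of 621 members, 483 had a named probe set and 420 passed the filter. Each list was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, using the probe set with the highest mean for each gene. Several members, such as ey, pros and gl, stand in more than 1 list.

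The genes named in the text follow a rule also fixed before the data were examined. They are run, sens, ro, w, ato, boss, loaf, pros and elav; per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called probe sets with 1 gene where the groups' arrays did not overlap; up to 10 genes called in both comparisons; and up to 4 members with the smallest p of each list. A gene's value is that of its probe set with the highest mean over the 12 arrays. Other genes were named after their values were seen, as were members beyond these 4 of a list. Where another probe set of a gene moved the other way and was called, the text says so.

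The filter, normalization, variance model, array weights, choice of arrays, replicate block, probe set summary and each replicate were varied in turn. After the data were seen, the rule for named genes and the list tests were repeated without Runt replicate 3, and the sens comparison and list tests were repeated without genes of chromosome 3. The model was tested on simulated data with 200 changed probe sets among 11470. In the simulated Runt comparison it recovered 53% of changes of 0.5 log2 units, 76.1% of changes of 1 and 97% of changes of 2. In the simulated sens comparison it recovered 45.5%, 80.6% and 95.5% of changes of those sizes. False calls numbered 14 in the simulated Runt comparison and 6 in the simulated sens comparison. The simulated noise had the same spread in all groups, and each change was equal in every array of a group. The recovered shares therefore do not apply where an array departs from its group, as Runt replicate 3 did. For arrays, the number of arrays limits the precision.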

Results

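Gene expression was profiled on 12 arrays of larval eye discs from 2 experiments of 6 arrays. In the first, the transcription factor Runt was expressed with ro-Gal4 in 3 samples and compared with 3 samples expressing Runt G163R. In the second, 3 samples homozygous for a sens mutant genotype were compared with 3 heterozygous controls. Runt and Senseless are transcription factors of the R7 and R8 photoreceptors, and the series concerns the targeting of the axons of these cells. Correlations between arrays of a group were 0.993 to 0.998, and between arrays of different experiments 0.976 to 0.986. No array duplicated another, with at most 1 identical value between any pair.

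The Runt comparison asks which transcripts differ between eye discs misexpressing wild-type Runt and discs misexpressing Runt G163R. No array of this experiment lacked a Runt transgene, so a change common to both forms is not seen. An effect of Runt G163R or of its line appears with the opposite sign. A rise or fall with Runt below is relative to Runt G163R. With all 3 Runt arrays, 5 probe sets were called, all with group means of 4.67 or lower. cGlr2, a cGAMP-synthase-like receptor, was higher in Runt discs by 0.67 (log2, SE 0.0581, adjusted p = 0.00186), and CG15147 by 0.49 (SE 0.0657, adjusted p = 0.0477). The call of CG15147 was lost in 11 of 16 alternatives. CG13005 fell by 0.47 (SE 0.0275, adjusted p = 0.000143). For cGlr2, CG15147 and CG13005 both groups lie in the floor, so these differences are compressed and their sizes approximate. A probe set of tutl, an immunoglobulin superfamily gene, rose by 0.85 (SE 0.0831, adjusted p = 0.00385), but it is not the brightest of that gene and 4 others tested for tutl were not called. Another, at 4.67 in Runt against 2.86, has no gene named here. The direction split of these calls, 80% higher, was 75% after a second quantile normalization and 100% after median subtraction, each with 4 calls. By limma, 729 of 11470 probe sets (6.36%) had an unadjusted p under 0.05, and 9.44% separated the groups without overlap, where chance gives 10%.

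This count depended on the processing and on Runt replicate 3. With all 6 Runt and Runt G163R arrays kept it was 466 with array weights, 0 with the 60th percentile filter, and 1 on these 6 arrays alone. Without Runt replicate 1 the count was 8 and without Runt G163R replicate 3 it was 12. Without Runt replicate 3, 119 probe sets were called, 63 higher and 56 lower, among them all 5 above, and 62 changed at least 2-fold. This set of arrays was singled out after the data were seen. The RING finger gene Rnf11 stood at 11.8 and 13.3 in Runt replicates 1 and 2, at 9.67 in replicate 3 and at 8.93 ± 0.119 (SD, n = 3) in Runt G163R. The homeobox gene vis was at 2.41 and 2.42 in replicates 1 and 2, at 4.79 in replicate 3 and at 5.79 ± 0.108 (SD, n = 3) in Runt G163R. For CG13005, in contrast, all 3 Runt arrays lay together at 2.47 ± 0.0152 (SD, n = 3), against 2.94 ± 0.0390 (SD, n = 3).

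**Figure D1:**
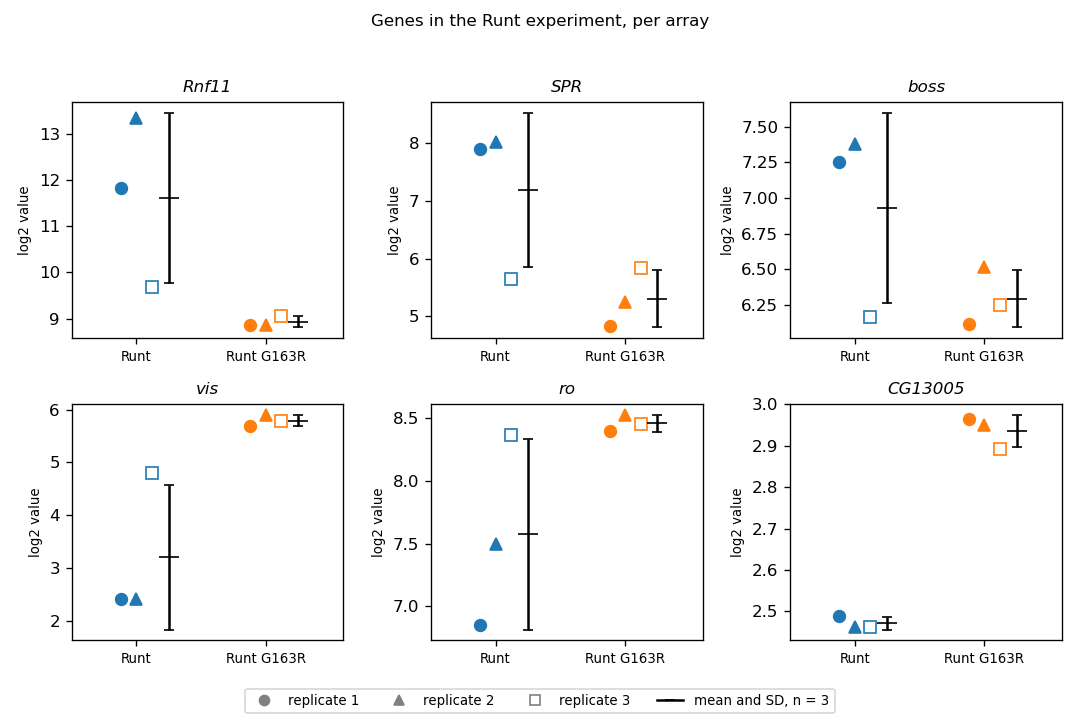
Log2 values per array of 6 genes in the Runt experiment, with the mean and SD of each group beside the points. Open squares are replicate 3; for Rnf11, SPR, boss, vis and ro the Runt replicate 3 value lies nearer the Runt G163R arrays than Runt replicates 1 and 2 do, and for CG13005 it does not.

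Among named genes, rises without Runt replicate 3 were led by Rnf11, at 3.65 (log2, SE 0.442, adjusted p = 0.00686, against 2.68 and adjusted p = 0.57 with all arrays), while its other probe set did not pass the test (2.58, adjusted p = 0.0741). The sex peptide receptor SPR rose by 2.66, CG15236 by 2.51, CG33143 by 2.48 and the receptor guanylyl cyclase Gyc32E by 2.06. CG17739 rose by 1.99, CG42458 by 1.98, CG7650 by 1.71 and the immunoglobulin superfamily gene klg by 1.67. The receptor tyrosine phosphatase Ptp10D rose by 2.21, while its other probe set fell by 1.33, so the direction of that gene is open. Among named genes, falls were led by vis, which fell by 3.38 (SE 0.0612, adjusted p = 1.47e-08) to values in the floor. The peptidoglycan recognition gene PGRP-LA fell by 2.56, alpha-Est10 by 2.54, CG3552 by 2.01, atilla by 1.95 and Root by 1.88. CG4259 and mthl2 each fell by 1.71, Eo by 1.68 and CG8245 by 1.67. Like vis, alpha-Est10 and Eo fell to values in the floor, with means of 2.67 and 2.30 in Runt replicates 1 and 2. The sizes of these falls are approximate. In the sens mutants and controls, vis (2.40 and 2.41) and Eo (2.30 and 2.29) also lay in the floor. For these genes the Runt G163R arrays and Runt replicate 3 stood apart. By the sens group means, PGRP-LA, CG3552, CG4259 and mthl2 were also nearer Runt replicates 1 and 2. The means of alpha-Est10, atilla, Root and CG8245 were nearer Runt G163R. The contrast cannot tell a fall with Runt from a rise with Runt G163R. None of these 20 genes was called with all 3 Runt arrays.

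Among the fixed genes, boss, which encodes the R8 ligand of Sevenless, rose by 1.02 without Runt replicate 3 (log2, SE 0.164, adjusted p = 0.0225). With all arrays the difference was 0.64 (SE 0.281, adjusted p = 0.773). ro, the homeobox gene whose regulatory DNA gives the driver its name, fell by 1.28 without that array (SE 0.201, adjusted p = 0.0205), and its difference was -0.89 (SE 0.304, adjusted p = 0.709) with it. For loaf the values were 0.86 (adjusted p = 0.0845) and 0.64 (adjusted p = 0.684). The proneural gene ato, pros, the pan-neuronal gene elav and sens itself did not pass the test in either fit, with differences of -0.23, 0.20, 0.47 and 0.03 over all arrays.

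By camera, 6 of the 27 lists were higher in Runt discs than other genes with all arrays. They were axon guidance and photoreceptor targeting (adjusted p = 0.000131), neuronal differentiation (0.0264), glia (0.0264), R7 genes (0.0371), brain and neuroblast markers (0.0371) and the JNK, JAK/STAT and wound response list (0.0371). No member of any of the 6 was called over all probe sets or adjusted over the list alone. With an estimated correlation the adjusted p values were 0.594, 0.713, 0.269, 0.713, 0.269 and 0.713, in that order, and no list was called. Without Runt replicate 3 axon guidance was the only list called by camera (adjusted p = 0.000171, and 0.668 with an estimated correlation), with Ptp10D as its only called member of 43 and 3 members adjusted over the list alone. Its members with the smallest p over all arrays, Ten-a, stan and NetB, had differences of 0.63, 0.34 and 0.50 (log2) that did not pass the test. In the detoxification list 1 member rose and 1 fell when adjusted over the list alone, with all arrays. They were Cyp6a17 at 0.88 and GstE5 at -1.01, neither called over all probe sets. With all arrays every other list had a camera adjusted p of 0.148 or more and no called member. These lists covered R8 and proneural genes, outer photoreceptor and cone cell determinants, Notch, EGFR, Hedgehog with Dpp and Wingless, retinal determination, cell cycle, apoptosis and phototransduction. They also covered ecdysone response, heat shock, immunity, eye pigment, dosage compensation, haemocyte, fat body, salivary gland, muscle, antenna and leg, and peripodial and cuticle genes. In several of them, such as the Notch and fat body lists, the mean difference was below 0 while camera pointed up.

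The sens comparison asks which transcripts change in eye discs that carry the sens mutant genotype. The transcript of sens itself was higher in the arrays labelled mutant, by 1.29 (log2, SE 0.173, adjusted p = 0.00112), at 10.8, 10.4 and 10.6 against 8.96, 9.30 and 9.61. The labels do not say whether the alleles remove transcript, so this probe set does not check the genotype, and directions below refer to the arrays as labelled. boss fell by 4.04 in the arrays labelled mutant (SE 0.281, adjusted p = 2.42e-05), from 6.46 ± 0.0676 to 2.42 ± 0.163 (SD, n = 3), where the mutant values lie in the floor and the size of the fall is therefore approximate. pros, a homeobox gene of R7 cells, fell by 1.27 (SE 0.216, adjusted p = 0.00372) and loaf by 0.92 (SE 0.206, adjusted p = 0.0142). ro, ato and elav did not pass the test, with differences of 0.67, 0.11 and -0.27.

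**Figure D2:**
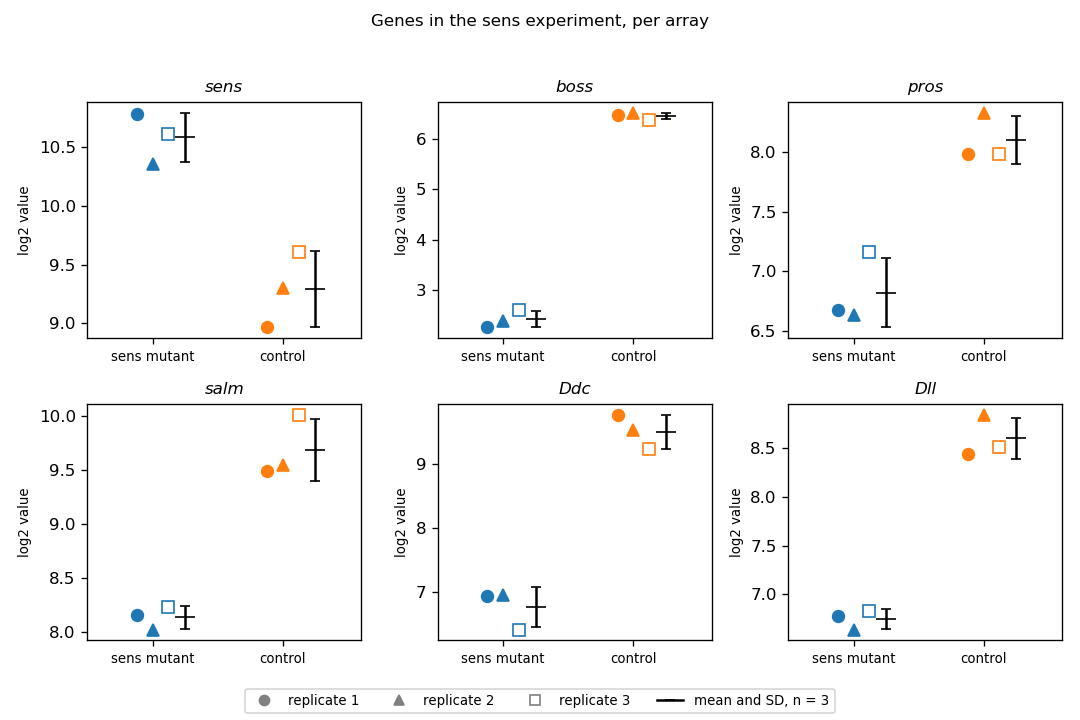
Log2 values per array of 6 genes in the sens experiment, with the mean and SD of each group beside the points. sens is higher in the 3 arrays labelled mutant, and boss, pros, salm, Ddc and Dll are lower there than in the 3 controls.

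In all, 1940 probe sets were called, 1332 higher and 608 lower in the mutant, and 1931 of them separated the groups without overlap. They covered 1659 named genes, while 221 of the called probe sets had several genes or none named. Of all probe sets tested, 38% did so, where chance gives 10%. At least 2-fold changes were seen for 227 higher and 252 lower probe sets. The share of calls that were higher, 68.7%, was set by the scaling. Without sens mutant replicate 1 the count was 1220. The share was 50.1% after a second quantile normalization and 29.7% after each array's median was subtracted, which moved the median difference of all probe sets from 0.0306 to -0.137.

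The largest differences above the controls were those of genes on chromosome 3. CG32055 rose by 7.05 (log2, SE 0.0682, adjusted p = 2.65e-12), from 2.19 in controls to 9.24, and was at 2.19 in the Runt G163R arrays. Hsc70-2, a heat shock cognate gene, rose by 5.24, the cyclin-dependent kinase gene Eip63E by 4.97, CG11357 by 4.94 and rosy (ry), the xanthine dehydrogenase gene, by 3.90. CG4074 rose by 3.67, the lipophorin receptor gene LpR2 by 3.51, Osi6 by 3.29, CHKov2 by 3.18 and l(3)87Df by 2.65. For several of these the controls were the group that stood apart. Hsc70-2 was at 7.61 in Runt G163R arrays, against 7.78 in mutants and 2.54 in controls, Eip63E at 10.9 against 11.3 and 6.33, and CG11357 at 7.55 against 8.48 and 3.54. CG4074, LpR2 and CHKov2 were also nearer the mutant level in Runt G163R, and ry, Osi6 and l(3)87Df nearer the control level, like CG32055. The largest printed falls were those of Mob2, by 7.75, GstD3, by 7.63 (SE 0.113, adjusted p = 9.35e-11), and the fatty acid elongase gene Elovl7, by 5.64. Another probe set of Mob2 did not pass the test, with a difference in the other direction (0.54, adjusted p = 0.247). Lcp65Af, a larval cuticle gene, fell by 4.44, CG15449 by 4.39, CG7408 by 4.16, be by 3.81, IA-2 by 3.77 and CG1894 by 3.66. Of these 10 falling genes, with boss, CG15449 and be lie on the X and IA-2 on 2L, and the others on chromosome 3. In Runt G163R arrays IA-2 (2.92) and CG7408 (4.21) were nearer the mutants than the controls, and the other 8 nearer the controls. Sizes and order are approximate where a group lies in the floor, as controls do for CG32055, Hsc70-2 and ry, and mutants for Mob2, Lcp65Af, CG15449, CG7408, IA-2 and boss. Another probe set of be did not pass the test (-0.17, adjusted p = 0.556). The size for CHKov2 is also approximate, with controls at 3.82, 6.57 and 6.94. Its difference ranged from 2.2 to 3.76 under alternatives, and its call was lost in 2 of 17.

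Chromosome 3 held 250 calls of at least 2-fold among 4090 probe sets (6.11%), against 156 of 5001 (3.12%) on the other arms. The odds ratio was 2.02 (95% interval 1.64 to 2.5, Fisher's exact p = 7.73e-12). It was 3.11 (2.26 to 4.33) for probe sets higher in the mutant and 1.37 (1.03 to 1.82) for those lower. Without the genes of chromosome 3, a setting added after seeing the data, 910 probe sets were called, 626 higher and 284 lower. That setting kept probe sets without a named arm, some of which may lie on chromosome 3. The gene sens lies on 3L. For the Runt calls without replicate 3 the odds ratio was 0.814 (0.517 to 1.27).

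**Figure D3:**
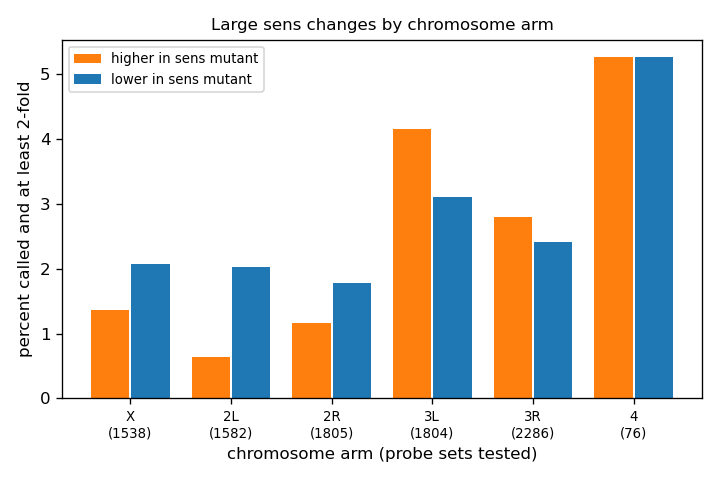
Percent of tested probe sets on each chromosome arm that were called and changed at least 2-fold in the sens comparison, split by direction, with the number tested under each arm. Both arms of chromosome 3 stand above X, 2L and 2R, with 7.26% and 5.21% in all against 3.45%, 2.65% and 2.94%; arm 4 has the highest share, 10.5%, with only 76 probe sets.

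Some members of the photoreceptor and neuronal lists fell in the arrays labelled mutant. In the R8 and proneural list 4 of 11 members fell, boss, the proneural cofactor gene nvy (by 1.46), ase (by 1.27) and phyl (by 0.50), and 1 rose, sens. In the R7 list 6 of 12 fell. Among them were pros, phyl, salr (by 1.40) and salm (by 1.54), the Spalt zinc-finger genes; sev, the Sevenless receptor gene, and NetB were the others. In the neuronal differentiation list 11 of 24 fell and 1, Hdc, rose by 1.42. The sodium pump subunit gene nrv3 fell by 1.15, nrm by 1.54, the calcium channel gene cac by 1.88 and Csp by 0.30. In the axon guidance and photoreceptor targeting list 14 of 43 fell and none rose. gogo, a receptor for photoreceptor axons, fell by 1.45 (SE 0.143, adjusted p = 0.000199), the protocadherin gene stan by 0.53, the Slit receptor gene robo1 by 1.80 and Alk by 0.18 near the floor. Adjusted over the list alone, 4 fell and 1 rose in the R8 list, 6 fell and 1 rose in R7, 12 fell and 2 rose in the neuronal list, and 14 fell in axon guidance. Camera gave adjusted p values of 0.00415, 0.000107, 1.91e-06 and 1.91e-06 for these 4 lists. With an estimated correlation each had an adjusted p of 0.177, so the list calls were lost. Of the falling genes, ase and pros also stand in the brain list and salm in the antenna list, described next. The neuroblast gene mira stood at 7.541, 7.889 and 7.714 in controls, at 6.417, 6.576 and 6.218 in mutants and at 6.38, 6.705 and 6.22 in Runt G163R. These falls therefore cannot be assigned to photoreceptors from these arrays. The mean of the R8 list was 7.94 to 8.13 in mutants, 8.45 to 8.72 in controls and 8.24 to 8.53 in the Runt experiment. For this list the mutants stood apart. For the R7, neuronal and axon guidance lists, the Runt G163R means overlapped those of mutants and of controls.

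Some markers of brain and of antennal tissue were also lower in mutants than in controls. In the brain and neuroblast list 7 of 17 members fell and 1, ey, rose. The dopa decarboxylase gene Ddc fell by 2.74 (SE 0.201, adjusted p = 3.11e-05), the neuroblast gene mira by 1.31, insc by 1.06 and ase by 1.27, with camera adjusted p = 1.45e-05 and 0.0231 with an estimated correlation. Adjusted over the list alone, 8 fell and 2 rose. In the antenna and leg disc list 4 of 14 fell, Dll by 1.84, al by 1.02, ap by 0.83 and salm by 1.54, with camera adjusted p = 0.00333 and 0.226 with an estimated correlation. Adjusted over the list alone, 5 fell and 2 rose. Lim1 of that list differed by -0.45 and did not pass the test (adjusted p = 0.512). Dll stood at 8.44, 8.84 and 8.51 in controls, at 6.78, 6.64 and 6.83 in mutants and at 5.33, 5.42 and 5.24 in Runt G163R. The mean of the brain list was 6.77 to 6.94 in controls, 6.17 to 6.20 in mutants and 6.08 to 6.29 in the Runt experiment, so for this list the controls stood apart.

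In the detoxification list 6 of 23 members fell, all glutathione S-transferase genes of the GstD cluster on 3R. GstD3 fell by 7.63, GstD1 by 1.20, GstD9 by 0.98 and GstD4 by 0.46, with camera adjusted p = 2.85e-05 and 0.03 with an estimated correlation, and 8 fell when adjusted over the list alone. None of its 14 members off chromosome 3 was called. The JNK, JAK/STAT and wound response list had 4 of 15 lower, GstD1, chinmo by 1.24, Jra by 0.46 and kay by 0.69 (camera adjusted p = 0.00333, and 0.209 with an estimated correlation), with 5 lower and 2 higher adjusted over the list alone. The calls of chinmo and kay were each lost in 9 of 17 alternatives. The haemocyte list had 1 of 19 lower, LanA by 0.69 (adjusted p = 0.00443, and 0.25 with an estimated correlation). The fat body list had 2 of 9 lower, Obp99a by 1.49 and Apoltp by 0.08 at the floor, a call lost in 10 of 16 alternatives (camera adjusted p = 0.00711, and 0.382 with an estimated correlation). In the same arrays the fat body gene Lsp2 ranged from 5.39 to 13.1 among the controls and from 5.18 to 10.5 among the mutants.

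The other lists were not called by camera in the sens comparison, with adjusted p values of 0.0987 or more. Some of their members were called. The retinal determination genes Optix, ey and toy rose by 0.89, 0.50 and 0.36, and gl fell by 0.47, of 11 tested. Cdk2, RnrL and Mcm2 rose by 0.77, 0.33 and 0.42 among 18 cell cycle genes. The caspase gene Dronc, Debcl and p53 rose by 0.66, 0.58 and 0.65 among 11 apoptosis genes, the call of p53 being lost in 6 of 17 alternatives. Eip63E, MsrA (by 1.13) and Hr4 (by 0.73, a call lost in 9 of 17 alternatives) rose among 20 genes of the ecdysone list. In the peripodial and cuticle list 4 of 16 rose, with TwdlT at 2.63, Cht5 at 1.99, Cpr97Ea at 1.20 and serp at 0.33, and 2 fell. Of 16 glial markers wrapper and moody rose by 1.29 and 0.41, and pyr, alrm and bdl fell by 1.03, 1.13 and 0.60. Act87E and sls of 13 muscle genes rose by 2.57 and 0.91, the call of sls being lost in 9 of 17 alternatives. ry and pr (by 0.46) of 12 pigment genes, and msl-3 (by 1.81) and tra2 (by 0.30) of 9 dosage compensation and sex genes, rose.

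In the Notch list Ocho rose by 0.88, while edl, H and mam fell by 0.46, 0.75 and 0.69, of 18 tested. In the EGFR list a probe set of Cbl rose by 1.93 while another fell by 1.29, so the direction of Cbl is open, and edl and spi fell by 0.46 and 0.28, of 15 tested, the call of spi being lost in 8 of 17 alternatives. onecut, gl and Sox21b fell by 1.22, 0.47 and 1.35 among 15 outer photoreceptor and cone cell determinants (Sox21b lost its call in 10 of 17 alternatives), inaE by 1.31 among 13 phototransduction genes (4 other probe sets of inaE were not called) and the antimicrobial peptide gene Mtk by 2.13 among 7 immune genes. The call of Mtk was lost in 6 of 16 alternatives. fkh fell by 0.14 at the floor, of 12 salivary gland genes. No member of the Hedgehog, Dpp and Wingless list (19 tested) or of the heat shock list (8 tested) was called. In the Notch, EGFR, Hedgehog, muscle and glia lists the mean difference was above 0 while camera, which sets a list against all other genes, pointed down. At least 1 other probe set of gogo, nrm, H, mam, kay, toy, sls and Hr4 was not called. In the peripodial list the median was -0.00784 and camera pointed up.

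The final comparison asks whether wild-type Runt, relative to Runt G163R, and the sens mutant genotype move the same genes in opposite directions. With all arrays no probe set was called in both comparisons, with only 5 calls on the Runt side. With medians subtracted 1 was, and with array weights 162 were. Of these 162, 69 rose with Runt and fell in the mutant, and 60 fell with Runt and rose in the mutant. Without Runt replicate 3, 35 were called in both. Of the 63 probe sets that rose with Runt, 14 fell in the arrays labelled sens mutant, where 3.37 are expected for independent lists. The odds ratio was 5.15 (95% interval 2.61 to 9.55, Fisher's exact p = 4.38e-06, adjusted p = 1.75e-05). This test treats probe sets as independent, which they are not, and uses arrays singled out after the data were seen. It does not measure replication. With Runt G163R replicate 3 left out instead, 1 probe set rose with Runt and fell in the mutant, among 12 Runt calls. With any other array left out there were 0, among 4 to 8 Runt calls. The other direction pairs held 7 against 7.61 expected (up in both), 8 against 6.77 (down, then up) and 6 against 2.99 (down in both), with adjusted p values of 1, 0.721 and 0.246.

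boss, SPR, Gyc32E, klg and CG17739 rose with Runt and fell in the mutant, in the fit without Runt replicate 3. Their differences in the mutant were -4.04 for boss, -2.89 for SPR, -2.23 for Gyc32E, -1.96 for klg and -1.48 for CG17739, where the mutant values of boss, SPR and Gyc32E lie in the floor and make the sizes approximate. With all arrays, the call of CG17739 in the mutant (adjusted p = 0.0441) was lost in 8 of 17 alternatives. CG7650 and Osi4 rose in both comparisons, by 1.71 and 1.48 with Runt and by 1.74 and 2.40 in the mutant. atilla, be and Root fell in both, by 1.95, 1.28 and 1.88 with Runt and by 2.56, 3.81 and 0.98 in the mutant. Another probe set of be was called in neither comparison. ro fell with Runt, by 1.28, and rose in the mutant, by 0.67, in this fit (adjusted p = 0.0335 in the mutant, against 0.167 with all arrays). Root was called in the mutant in this fit (adjusted p = 0.0276) and with only the 6 arrays (0.0416), and was not called with all 12 (0.186). Across all 11470 probe sets the fold changes of the experiments correlated at -0.121 (Pearson, -0.17 with all arrays), as a description over probe sets that are not independent replicates.

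**Figure D4:**
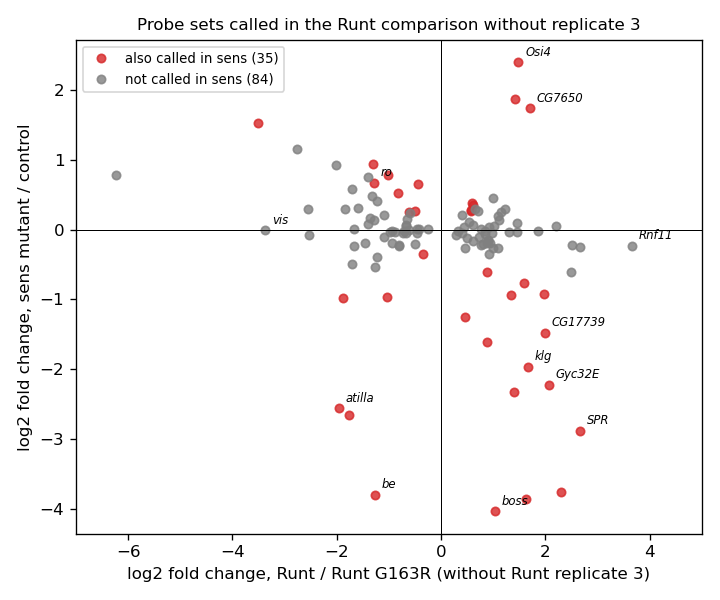
Log2 fold changes of the 119 probe sets called in the Runt comparison without replicate 3, set against those of the sens comparison. Red points are the 35 also called in the sens comparison, of which 14, including boss, SPR, Gyc32E and klg, lie at the lower right.

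The change differed between the experiments for 1157 probe sets, 384 with a larger value for Runt and 773 with a smaller value, by the limma test of the difference with all 12 arrays. The share with a larger value, 33.2%, was 54.3% after a second quantile normalization and 74% after median subtraction. The count was 2669 with array weights. It was 702 without sens mutant replicate 1 and 718 without sens mutant replicate 3. It was 710 without Runt replicate 2, 747 without Runt G163R replicate 1 and 724 without Runt G163R replicate 2. With the real sens groups and other groupings of the Runt arrays it was 406 to 1730, so its size came mostly from the sens comparison. The difference was 4.68 for boss (adjusted p = 0.000202), 4.77 for SPR (adjusted p = 0.00666), 3.81 for Gyc32E (adjusted p = 0.00487) and 3.19 for klg (adjusted p = 0.00384), approximate for boss, SPR and Gyc32E for the same reason of the floor. For loaf it was 1.56 (adjusted p = 0.0104) and for pros 1.47 (adjusted p = 0.0162). For ro it was -1.55 (adjusted p = 0.049). A preparation difference shared by all arrays of an experiment cancels in this contrast only where it shifts their log2 values equally. It does not cancel where it puts 1 experiment in the floor, since differences there are compressed. A difference shared by all arrays of an experiment was seen for the 18S rRNA control. Its 5′ probe set lay between 10.7 and 12.2 in the Runt experiment and between 5.76 and 6.43 in the sens experiment.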

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

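The tests in this part were chosen after the results were seen, except the counts over other splits of the arrays, of which only the comparison by sens groups was added later. Groups of 3 are too small for a test of single outlying arrays, and no control probe set was higher in every treated array than in every control by 1 log2 unit, so no value is listed here on those grounds.

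Runt replicate 3 lay near the Runt G163R arrays on most genes that separated Runt replicates 1 and 2 from them, such as Rnf11, vis and boss. Over the 119 probe sets called without it, it was nearer the Runt mean on 11.8%, while Runt G163R arrays held out in the same way reached up to 19.6%. The 75th percentile of its position between the Runt G163R mean (0) and the Runt mean (1) was 0.272. Replicates 1 and 2 both chose these probe sets and set position 1, which favours lower positions for any other array. No Runt array with a response was held out in the same way. The position therefore cannot decide whether the log2 response of replicate 3 reached 0.5 of that in replicates 1 and 2. A smaller response stays open, since its median position of 0.0915 lay among held-out values of 0.0266 to 0.132, and vis (4.79, against 5.79 ± 0.108) and Rnf11 (9.67, against 8.93 ± 0.119) lay between the groups. However, vis also lay in the floor in the sens mutants (2.40) and controls (2.41). Its value therefore cannot tell a smaller fall with Runt from part of a signal of the Runt G163R arrays, as in a mixed sample. The values are consistent with an array that lacks most or all of the response; a wrong label, a mixed sample, larvae without Runt expression, or a difference unrelated to Runt that replicates 1 and 2 share stay open, and no biological explanation was tested.

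Large changes in the sens comparison were concentrated on chromosome 3, where Mob2, GstD3, CG32055 and Eip63E lie. The odds ratio of 2.02 argues against loss of sens acting wherever genes lie as the whole cause, although boss and other genes may still respond to it. A heterozygous control that shares 1 copy of chromosome 3 with the mutant should keep about 50% of a cis-controlled level, yet 18 probe sets bright in the control were higher in the mutant by more than 2-fold at the 95% bound, against 1 on the other arms, which argues against cis dosage as the whole cause. The 200 genes nearest sens had no excess over the rest of the chromosome (odds ratio 0.953, 95% interval 0.491 to 1.7), which argues against a difference in that region alone. Cis dosage for the other genes, among them the 111 lower by at least 2-fold, and a difference in genetic background along the whole chromosome stay open and were not tested.

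The sens transcript was higher in the arrays labelled mutant. If loss of sens lowers the R8 gene boss, an exchange of the mutant and control labels would put boss higher in the arrays labelled mutant. Its difference was -4.04. However, boss lies on 3R, where a difference in genetic background stays open, so its value alone cannot exclude exchanged labels. Scaling between arrays did not remove the rise of sens, since the lower of its values under other scalings was 1.12. An effect of the mutant genotype on the sens transcript stays open and was not tested.

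The 6 arrays of each experiment make 10 splits, too few for a share under 0.05. The Runt comparison called 5 probe sets; 2 of its 10 splits gave as many, and the highest other split gave 5. The sens comparison called 1940, reached by 1 of 10 splits, and the highest other split gave 15. For the gene lists, the Runt comparison called 6, reached by 3 of 10 splits with 6 as the highest other, and the sens comparison called 10, reached by 1 of 10 with 9 as the highest other. For calls in both comparisons, 0 with the real groups, all 100 combined splits gave as many and the highest other was 0. A count of 0 is reached by every split, so this share carries no information. The overlap without Runt replicate 3 was not put through splits. For the difference between experiments, 1157, 2 of 100 splits drawn gave as many and the highest other gave 1730. The 10 drawn splits that kept the real sens groups gave 406 to 1730, and the other 90 at most 16, so this count follows the sens groups, and its low share does not exclude chance for the Runt groups.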

How the results depend on the processing

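Alternatives without chromosome 3 genes and list tests without Runt replicate 3 were chosen after the data were seen. Among values of named genes under alternatives, 2689 kept their direction and side of the threshold, 149 lost and 113 gained a call, and 7 changed sign, none of them called in the main result. The cause of the changes below was not tested unless stated. Calls by Runt, 5 in the main result, were 0 with the 60th percentile filter, 466 with array weights and 1 on only the 6 arrays. They were 0 with an ordinary linear model on these 6, 2 per gene and 4 or 5 without a filter and under other scalings and prior variances. The array weights were 0.827, 2.62 and 0.443 for Runt replicates 1 to 3 and 0.545, 5.26 and 0.932 for Runt G163R. The 466 calls thus lean mainly on replicate 2 of each group, and not only on a lower weight of Runt replicate 3. Calls by Runt ranged from 6 to 119 with an array of the Runt experiment left out, and were 4 with any 1 array of the sens experiment left out. Calls in sens mutants, 1940, were 1407 on only the 6 arrays and 675 with the ordinary linear model on them, which has fewer degrees of freedom. They were 910 without chromosome 3 and 406 without chromosomes 2 and 3, as fewer probe sets were tested. Both of these settings kept probe sets without a named arm, some of which may lie on the chromosomes left out. With replicates left out the calls ranged from 1220 to 2009. Calls in both, 0, were 1 with medians subtracted and 162 with array weights, and ranged from 0 to 35. Calls of a difference between experiments, 1157, were 2669 with array weights and ranged from 702 to 1327; they could not be had from 6 arrays. Lists called by camera for Runt, 6, were 0 with an estimated correlation, 0 by fry, 1 without Runt replicate 3 and 3 without chromosome 3. For sens, 10, they were 2 with an estimated correlation and 16 by fry.

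Replicate numbers did not pair the samples: same-numbered arrays correlated in their deviations at 0.256, -0.121 and 0.0646 in the Runt experiment and at -0.42, -0.0674 and 0.0756 in the sens experiment. With a replicate block, 1 probe set was called for Runt, 1564 for sens, 0 in both and 817 for the difference. Sign changes were seen only for ato and sens among named genes. In the sens comparison ato, 0.11, was -0.0555 after quantile normalization again and -0.0609 after median subtraction, and ranged from -0.12 to 0.48 with replicates left out, with -0.03 without control replicate 2. In the Runt comparison ato, -0.23, was 0.046 with array weights, and sens, 0.03, ranged from -0.0843 to 0.145 with replicates left out, with -0.03 without Runt G163R replicate 1. A pseudocount was not run, since the values are logarithms.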

Other observations

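Genes of other larval tissues differed widely between arrays of the same group; these genes were chosen after their values were seen, from the fixed marker lists. The fat body gene Fbp1 stood at 11.9, 6.30 and 3.24 in the sens controls and at 5.31, 10.3 and 2.67 in the mutants. Eig71Ea, a gene of the late larval ecdysone response, stood at 2.46, 12.9 and 11.5 in the mutants, at 10.7, 5.67 and 2.41 in the controls and between 2.40 and 2.42 in the Runt experiment. The glue gene Sgs8 was at 9.34 and 8.29 in mutants 2 and 3, at 6.58 in Runt replicate 3 and at 6.31 in Runt G163R replicate 2.

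Blood cell genes separated the experiments. The prophenoloxidase gene PPO1 lay between 8.52 and 11.1 in the 6 arrays of the Runt experiment and between 2.03 and 2.76 in the sens arrays. PPO2 lay between 9.50 and 12.2 against 3.28 to 4.67, and Hml between 7.09 and 8.68 against 2.64 to 3.25. The mean of the 19 haemocyte markers was 8.52 to 9.17 in the Runt experiment and 6.05 to 6.87 in the sens experiment.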
